A study of Homo sapiens with 13 samples.

How the data were processed

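The samples were HSC and GMP sorted from the bone marrow of CD99 knockout mice and wild-type littermates on a C57Bl/6 background, with libraries made with a SMARTer mRNA kit, per the labels. The labels name human as the organism, while every gene identifier is a mouse Ensembl identifier; the values were therefore read as mouse. The 13 libraries form 4 groups: GMP wild type (n = 3), GMP knockout (n = 3), HSC wild type (n = 3) and HSC knockout (n = 4). The labels do not say which replicates come from which animal, so the p-values measure the spread between samples. Replicate numbers were not used as pairs, because residual profiles of wild-type and knockout libraries with the same number had correlations from -0.52 to 0.049 and only 1 of 6 was the best match of its number. No batch or date is given.

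The authors processed the reads with STAR, HTSeq and RSEM, per the labels, with no versions; the genome build and annotation are not stated, so no coordinates are given here. The deposited gene tables hold RSEM expected counts, which are not normalized, together with TPM (transcripts scaled to a fixed total) and FPKM (fragments per kilobase of effective length, scaled to a fixed total). Expected counts, rounded to whole numbers, were used for all tests; the deposited TPM values were used in 1 alternative, and the deposited FPKM values and the isoform tables were not used here. The tables have 43309 genes, of which 3 have no symbol, and 58 symbols belong to more than 1 gene. No gene has the symbol Cd99, so its level and fold change are not analysed here. Library totals were 28181500 to 44825500 expected counts in GMP wild type, 26658400 to 34626400 in GMP knockout, 27328300 to 28356800 in HSC wild type and 26956500 to 33780400 in HSC knockout. Between 15582 and 19753 genes were detected per library, and the 50 most abundant genes took 15.5% to 16.4% of counts in GMP and 9.66% to 10.2% in HSC. Reads without molecular identifiers are not independent molecules, so a floor of 3 counts, used where a group is at 0, covers counting error only.

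Libraries of the same group were checked for duplicates: the chi-square per degree of freedom between 2 libraries of a group, over genes with at least 10 counts, was 21.3 to 93.0 over 15 pairs. Transcripts that mark the X-inactivation center and the Y chromosome were found together in 2 of 13 libraries; these genes are not reported here.

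Genes were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr with the groups, TMM factors, quasi-likelihood F test, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. GMP and HSC knockout against wild type were fitted within each cell type, the wild-type populations in a fit of the 6 wild-type libraries, and the difference of the knockout effects (HSC minus GMP) and their average in a fit of all 13. A fixed set of 36 gene lists for lineage, cell cycle, metabolism, protein synthesis and stress was written from general knowledge; 35 had at least 5 measured genes, and 22 members matched no symbol. Lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over the lists tested; camera with an estimated correlation and fry were alternatives. A list's median for the knockout comparisons is over log2 CPM differences, and for the wild-type populations over fitted log2 fold changes. Levels of groups in the text are CPM with TMM scaling within the comparison; plots, captions and levels of single libraries in the closing parts are CPM of the library total. Plots were drawn with matplotlib 3.10.9 (Python 3.11.15).

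The comparisons, tests, gene lists and the rule for named genes were chosen before the data were examined. The rule names genes past the threshold with a mean log2 CPM of at least 1 and no overlap between groups. Where fewer than 5 pass in a direction, it adds those of smallest p up to 5, as not passing. These meet the same conditions on level and overlap, so their separation follows from the rule. For the interaction it names the genes of smallest p. It also names up to 4 members of smallest p of each list described. For the wild-type populations it names the genes of the sort gates and the most abundant HSC-enriched and granule genes. Predicted gene models and sex-linked genes were left out. The correlation of the knockout effects was tested against 100 regroupings of the genotypes within each cell type. The count of genes past an unadjusted p of 0.005 in both cell types was added after the results were seen. It was tested against the same regroupings.

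Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a filter of 10 counts in every sample of a group, limma-trend on log2(TPM + 1) with a mean TPM of at least 1, a threshold of 0.1, the replicate number as a block, all 13 libraries in 1 fit, the 50 most abundant genes left out (for the difference of effects), a mean log2 CPM of at least 4 (for the overlap), and each library left out in turn. Added after the data were seen were edgeR with robust=TRUE, the share of HSC-type transcripts as a covariate, a fit without the libraries that stand apart (GMP wild-type replicate 3, GMP knockout replicates 1 and 2, HSC knockout replicate 1) and the average knockout effect. Simulated data, with each gene drawn on its own, were used to test the models. Each data set had 1 shifted list. In the same data, 100 genes with a log2 CPM of at least 1 changed 2-fold and 100 changed 4-fold. edgeR recovered 65 and 92 of them in GMP with 21 false calls, 43 and 86 in HSC with 4, 25 and 65 for the difference of effects with 5, and 40 and 72 for the wild-type populations with 9. DESeq2 recovered 74 and 97 in GMP with 67 false calls, 58 and 89 in HSC with 53, 42 and 81 for the difference of effects with 52, and 67 and 89 for the wild-type populations with 77. A shift of 0.5 given to 1 list was recovered in all 4 designs with 0 of 34 other lists called. Because simulated genes were independent, this does not test false list calls where genes move together. In the real libraries the estimated correlation was 0.74 for HSC-enriched genes in GMP.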

Results

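RNA was sequenced from 2 populations sorted from the bone marrow of CD99 knockout mice and wild-type littermates. Hematopoietic stem cells (HSC) were gated as lineage-negative, c-Kit+, Sca-1+, CD150+ and CD34-, and granulocyte-macrophage progenitors (GMP) as lineage-negative, c-Kit+, Sca-1-, CD16/32+ and CD34+. There were 3 wild-type and 3 knockout GMP libraries, and 3 wild-type and 4 knockout HSC libraries. CD99 is a cell-surface glycoprotein of leukocytes and stem cells, and the series concerns its part in stem cell self-renewal and protein synthesis. The level of the targeted gene itself is not analysed here, because no gene in the tables carried the symbol Cd99. Levels are CPM, counts scaled to a common library size, after TMM scaling, or CPM of library total where so named. They are given as mean ± SD over the libraries of a group, and log2 fold changes are given ± SE. Unless another tool is named, adjusted p is the Benjamini-Hochberg value of the edgeR quasi-likelihood test for genes and of limma camera for gene lists.

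The sort-gate transcripts listed here differed between the 2 populations in the direction of the gates, though Cd34 mRNA was present in HSC. In wild-type libraries Ly6a, which encodes Sca-1, had 8.41 ± 12.0 CPM in GMP and 222 ± 25.5 in HSC. Slamf1, which encodes CD150, had 1.72 ± 2.57 and 54.2 ± 12.9. Cd34 had 613 ± 43.0 CPM in GMP and 196 ± 58.9 in HSC, and Fcgr3 of the CD16/32 gate had 566 ± 13 and 0.908 ± 0.846. Myeloperoxidase mRNA (Mpo) had 55016 ± 2249 CPM in GMP and 8.48 ± 9.75 in HSC. All 27 GMP and primary granule genes were lower in HSC past the threshold, with a median log2 difference of -5.69. Of 40 HSC-enriched genes, 39 were higher in HSC, with a median of 4.49, among them Angpt1 (log2 3.65 ± 0.42, adjusted p = 3.9e-04).

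The cell cycle and growth programs separated the 2 wild-type populations. Counts of genes higher or lower between these populations are of those past the threshold, while those given for knockout lists count direction alone. All 40 mitosis genes measured were lower in HSC, with a median log2 difference of -3.29. Aurkb went from 352 ± 36.7 CPM in GMP to 19.4 ± 1.33 in HSC (log2 -4.18 ± 0.12, adjusted p = 2.2e-06). S-phase genes were lower in 42 of 44 cases, with a median of -1.61 and Rrm2 at -3.98 ± 0.16. Nuclear-encoded oxidative phosphorylation genes were lower in 74 of 75 cases, with a median of -1.07. Atp5b went from 2501 ± 114 to 1147 ± 26.8 CPM. MYC and its canonical targets were lower for 36 and higher for 3 of 41 genes, with a median of -1.28. Interferon-stimulated genes went the other way: 42 of 48 were higher in HSC, with a median of 2.03. Oasl2 went from 16.5 ± 5.20 to 150 ± 8.25 CPM.

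The machinery of protein synthesis was also less abundant in wild-type HSC than in GMP. Translation initiation and elongation factors were lower for 41 and higher for 3 of 53 genes, with a median of -0.67. Eif4a1 went from 1743 ± 76.6 to 471 ± 22.3 CPM while its paralog Eif4a2 went from 138 ± 13.4 to 392 ± 20.3. Ribosome biogenesis genes were lower for 62 of 81, with a median of -0.71 and Npm1 at -1.11 ± 0.08. Cytosolic ribosomal protein genes were lower for 60 and higher for 1 of 82, with a median of -0.53. The size of these differences depended on the scaling, since the median of all genes lay at 0.020 with TMM, 0.12 with DESeq2 or RLE size factors, 0.24 with upper-quartile factors and 0.46 on log2 TPM. Relative to that median, the ribosomal protein median lay between -0.55 and -0.47 over the 5 scalings. Its own value on log2 TPM was -0.0076, with 27 genes higher and 22 lower. In all, 7926 of 14451 genes differed between the wild-type populations, 3911 higher and 4015 lower in HSC. This split depended on the scaling, with 4817 higher and 3114 lower with upper-quartile factors and 6357 and 2236 on log2 TPM. The total lay between 6236 and 7602 with 1 library left out, 6236 without GMP wild-type replicate 2.

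**Figure D1:**
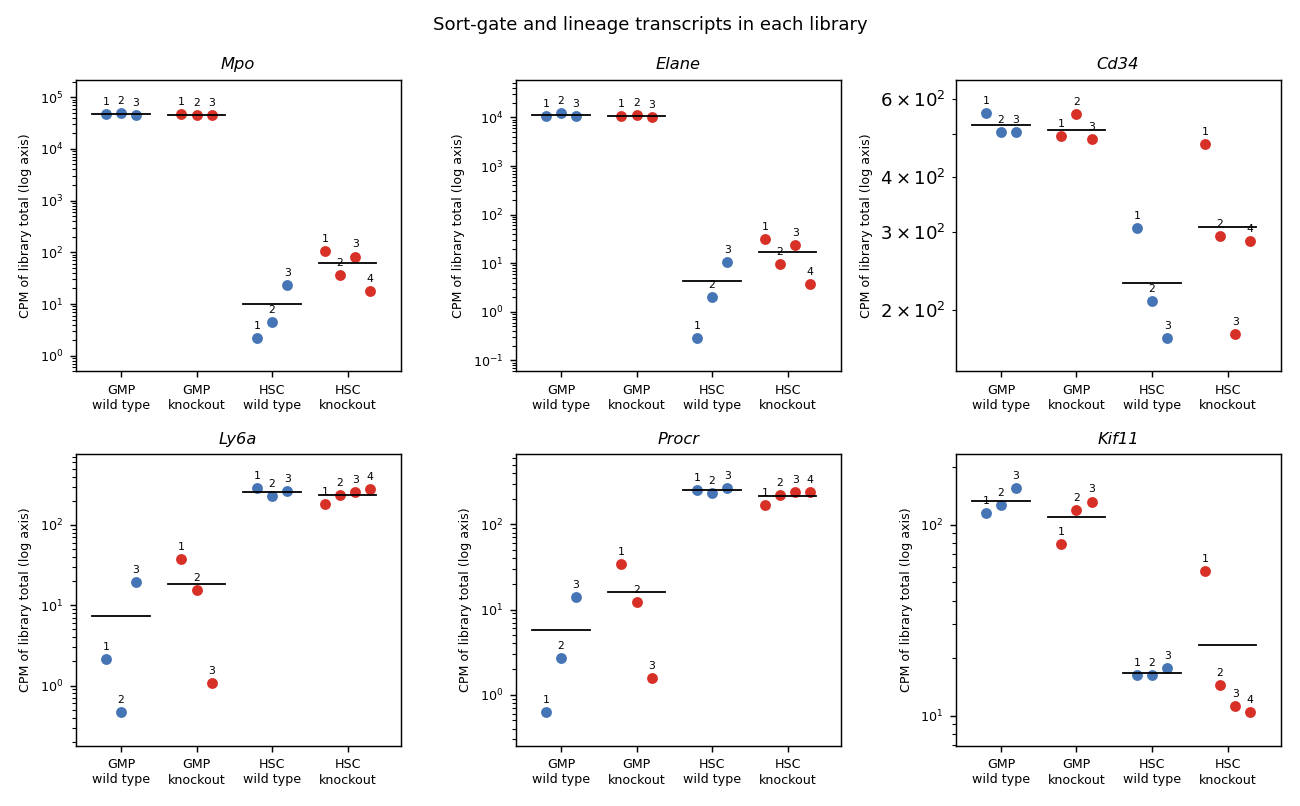
CPM of library total (log axis) of Mpo, Elane, Cd34, Ly6a, Procr and Kif11 in each of the 13 libraries, as points numbered by replicate with the group mean as a line, wild type in blue and knockout in red. Among GMP libraries Ly6a was 19.3, 37.9 and 15.6 in wild-type replicate 3 and knockout replicates 1 and 2, against 0.467 to 2.12 in the other 3, and Kif11 was 57.2 in HSC knockout replicate 1.

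In GMP knockout libraries 1 transcript, Fam118a (ENSMUSG00000022434), was nearly lost. It had 28.2 ± 2.58 CPM in wild type (n = 3) and 3.33 ± 0.681 in knockout (n = 3), a log2 fold change of -3.08 ± 0.21 (adjusted p = 0.00694). It was lower in 3 of 3 knockout libraries, which the rule for named genes requires. It was the 1 gene past an adjusted p of 0.05 among 13675 tested. There were 469 genes with an unadjusted p under 0.05. DESeq2 called 8 genes and limma on log2 TPM called 2. Genes next in rank that did not pass with edgeR included Ide (ENSMUSG00000056999), the insulin-degrading enzyme, at 350 ± 54.1 and 189 ± 17.6 CPM (log2 -0.89 ± 0.13, adjusted p = 0.762). Btaf1, a regulator of the TATA-binding protein, had 37.6 ± 3.83 and 22.8 ± 3.76 CPM. Wdfy1 (ENSMUSG00000073643) had 69.4 ± 9.42 and 121 ± 6.07 CPM (log2 0.80 ± 0.12, adjusted p = 0.762). The adhesion molecule gene Icam1 had 17.4 ± 1.22 and 34.1 ± 7.19 CPM, Jak3 55.4 ± 10.9 and 92.4 ± 6.65. Klf9 had 17.2 ± 2.63 and 31.2 ± 3.61 CPM and Creld2 140 ± 3.08 and 185 ± 15.1. Slpi (353 ± 47.5 and 262 ± 19.2 CPM) and Cep164 (14.7 ± 0.738 and 9.41 ± 0.706) complete the genes of smallest p among those without overlap between groups. Neither passed with edgeR or DESeq2. Of the others, DESeq2 called Ide (adjusted p = 4.8e-08), Wdfy1 (1.5e-06), Icam1 (0.0114), Jak3 (0.0166), Klf9 (0.020) and Creld2 (0.0277), and not Btaf1. In simulated counts of the GMP design DESeq2 made 67 false calls and edgeR 21.

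The size of the Fam118a difference in GMP lay between -3.39 and -2.51 over 17 alternatives. Of these, 10 left it past the threshold (adjusted p 6.1e-34 to 0.182). It was not past it without wild-type replicate 1 (-3.02, adjusted p = 0.103), wild-type replicate 2 (-3.15, 0.0545), wild-type replicate 3 (-3.08, 0.0578) or knockout replicate 2 (-3.07, 0.181). The call also ended with the replicate number as a block (-3.10, 0.182), with all 13 libraries in 1 fit (-3.02, 0.0525) and without the libraries that stand apart (-3.39, 0.133), which leaves 1 knockout library. Groups did not overlap for 1319 genes in GMP, 9.65% of those tested, where chance gives 10%.

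In GMP knockout libraries 15 of 35 gene lists were past an adjusted p of 0.05 with the preset correlation between genes (8 higher, 7 lower). None was with a correlation estimated from these libraries (adjusted p = 0.737 with an estimated correlation for each of the 15) or with fry. Without wild-type replicate 1, 6 lists passed, and 7 without knockout replicate 1. HSC-enriched genes were higher for 39 of 40 members, with a median log2 fold change of 1.33 (adjusted p = 8.2e-08; adjusted p = 0.737 with an estimated correlation). Ifitm1 had 38.9 CPM in wild type and 94.5 in knockout and Hoxa9 27.2 and 38.6. This list was highest in 3 libraries across both genotypes, though every knockout library lay above wild-type replicates 1 and 2. A part from the genotype therefore cannot be told apart. Its score was 2.06 in wild-type replicate 3 and 2.84 and 1.78 in knockout replicates 1 and 2, against -1.20, -0.86 and 0.24 in wild-type replicates 1 and 2 and knockout replicate 3. Its median was 0.60 without knockout replicate 1, 2.01 without wild-type replicate 3 and 2.37 without knockout replicate 3, each past the threshold. Oxidative phosphorylation genes were lower for 73 of 75 members, with a median of -0.11 (adjusted p = 9.5e-08). Mitosis genes were lower for 37 of 40, with a median of -0.21 (adjusted p = 1.3e-07). The adjusted p = 0.737 with an estimated correlation for both lists. The mitosis median was -0.072 without knockout replicate 1, still past the threshold. That library had a mitosis score of -0.50, while knockout replicates 2 and 3 (-0.071 and -0.043) lay above wild-type replicate 1 (-0.10). Without wild-type replicate 1 the oxidative phosphorylation median was -0.046 and not past the threshold, and it was -0.19 without wild-type replicate 3. Cytosolic ribosomal protein genes were lower for 77 of 82 members, by a median of -0.059 (adjusted p = 7.0e-04; adjusted p = 0.737 with an estimated correlation). The call ended without wild-type replicate 1 (-0.012), and the median was -0.12 without wild-type replicate 3. Relative to all genes it was -0.066 to -0.042 over the scalings tried. The ribosomal protein score was -0.12 in wild-type replicate 3, lower than in any knockout library (-0.089, -0.070 and -0.029). The oxidative phosphorylation score of that library, -0.13, was within the knockout range of -0.16 to -0.081.

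Of the lists closest to the study's question on protein synthesis in GMP, translation initiation and elongation factors (median -0.0047, adjusted p = 0.522) and MYC targets (median -0.023, mean 0.12, adjusted p = 0.794) did not pass. Ribosome biogenesis genes did not pass either (adjusted p = 0.746), with a median of 0.0052, a mean of -0.013 and a test direction of lower. Mitochondrial ribosomal protein genes had a median of -0.066 (adjusted p = 0.00275; adjusted p = 0.737 with an estimated correlation), and the call ended without wild-type replicate 1 (-0.016) or knockout replicate 1 (-0.026). It held at -0.13 without wild-type replicate 3. Unfolded protein response genes had a median of 0.11 (adjusted p = 0.0203; adjusted p = 0.737 with an estimated correlation), with Hspa5 at 2635 CPM in wild type and 3075 in knockout. The list was not past the threshold without wild-type replicate 1 (0.092), wild-type replicate 3 (0.10) or knockout replicate 3 (0.068). Proteasome genes had a median of -0.093 (adjusted p = 9.98e-04; adjusted p = 0.737 with an estimated correlation), and the call ended without wild-type replicate 1 (-0.024) or knockout replicate 1 (-0.043).

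Among lineage lists in GMP, GMP and primary granule genes were lower in knockout for 20 of 27 members with a median of -0.11 (adjusted p = 0.0112; adjusted p = 0.737 with an estimated correlation), including Clec12a at 790 and 601 CPM. The call ended without wild-type replicate 2 (-0.043) or knockout replicate 1 (-0.030). Megakaryocyte and platelet genes were higher for 20 of 21 members, with a median of 0.87 (adjusted p = 4.1e-04; adjusted p = 0.737 with an estimated correlation), which was 0.29 and not past the threshold without wild-type replicate 2. It was 0.46 without wild-type replicate 1, 1.86 without wild-type replicate 3 and 1.45 without knockout replicate 2. Over fitted fold changes the median was 0.50 (0.49 to 0.55 over scalings). Their score was 1.74 in wild-type replicate 3, above the 3 knockout libraries (1.38, 0.59 and 1.45). Erythroid genes had a median of 1.03 (adjusted p = 0.0241; adjusted p = 0.737 with an estimated correlation). They did not pass without wild-type replicate 1 (0.65), wild-type replicate 2 (0.16), knockout replicate 1 (0.83) or knockout replicate 3 (0.73), and the median was 1.84 without wild-type replicate 3. Fitted fold changes gave 0.44 (0.42 to 0.44 over scalings). Their score was likewise highest in wild-type replicate 3, at 1.45, against 1.11, 0.47 and 1.13 in knockout. Knockout replicate 3, with few HSC-type transcripts, had erythroid and megakaryocyte genes at 5.87 times the share of other HSC-type genes. NF-kB targets had a median of 0.75 (adjusted p = 0.00694; adjusted p = 0.737 with an estimated correlation), with 0.25 and no call without knockout replicate 1 and 0.41 without wild-type replicate 2. Their fitted fold changes gave 0.45 to 0.73 over scalings. In that list 1 gene, Icam1, was higher when adjusted over the list alone, against 0 over all genes tested by edgeR. Immediate early genes had a median of 0.56 (adjusted p = 0.00108; adjusted p = 0.737 with an estimated correlation), with Junb at 76.5 and 153 CPM. They did not pass without wild-type replicate 1 (0.31), wild-type replicate 2 (0.33) or knockout replicate 1 (0.16), and had 0.86 without wild-type replicate 3. Both lists were highest in the 3 libraries with HSC-type transcripts. In wild-type replicate 3 and knockout replicates 1 and 2 the NF-kB score was 0.55, 1.22 and 0.80, against -0.28, -0.27 and -0.037 in wild-type replicates 1 and 2 and knockout replicate 3. The immediate early score was 0.96, 1.60 and 0.75 against -0.54, -0.42 and 0.044.

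The last 3 lists called in GMP were close to the threshold. Interferon-stimulated genes (median 0.22, adjusted p = 0.0241), S-phase genes (median -0.069, adjusted p = 0.0328) and cholesterol biosynthesis genes (median 0.081, adjusted p = 0.0384) each had an adjusted p = 0.737 with an estimated correlation. The interferon list did not pass without wild-type replicate 1 (0.20), wild-type replicate 2 (0.15) or knockout replicate 1 (0.086, with the test direction reversed). Its score was 0.60, 1.09 and 0.45 in wild-type replicate 3 and knockout replicates 1 and 2, and -0.28 in knockout replicate 3, near wild-type replicates 1 and 2 (-0.32 and -0.27). The median was 0.37 without wild-type replicate 3 and 0.49 without knockout replicate 3. The S-phase list did not pass without wild-type replicate 1 (-0.049), wild-type replicate 2 (-0.052), knockout replicate 1 (-0.012) or knockout replicate 2 (-0.073). The cholesterol list did not pass without wild-type replicate 1 (0.065), wild-type replicate 3 (0.099) or knockout replicates 1 (0.051), 2 (0.12) or 3 (0.097), and had 0.14 without wild-type replicate 2.

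In HSC no gene passed the threshold, and Fam118a was again among those of smallest p. It had 30.8 ± 2.13 CPM in wild type (n = 3) and 4.69 ± 1.99 in knockout (n = 4), a log2 fold change of -2.71 ± 0.37 (adjusted p = 0.269). Ube2e2 (ENSMUSG00000058317), a ubiquitin-conjugating enzyme, had 58.6 ± 7.78 and 12.1 ± 4.08 CPM (log2 -2.28 ± 0.29, adjusted p = 0.269). Max (ENSMUSG00000059436), the dimerization partner of MYC, had 78.2 ± 16.4 and 37.6 ± 5.18 (log2 -1.05 ± 0.18, adjusted p = 0.748). Ide had 231 ± 41.0 and 134 ± 10.5 CPM and Btaf1 38.9 ± 6.33 and 19.6 ± 3.31. All 5 genes were lower in 4 of 4 knockout libraries than in every wild-type library, which the rule for named genes requires. Higher in knockout were Taf4b (12.7 ± 0.872 and 23.8 ± 2.83 CPM), N4bp3 (5.47 ± 0.568 and 12.6 ± 1.96), Tnfaip8 (260 ± 5.49 and 342 ± 25.8), Vldlr (20.1 ± 3.25 and 37.1 ± 6.72) and the inducible HSP70 gene Hspa1b (6.46 ± 1.77 and 87.1 ± 70.8). None of the 10 genes passed with edgeR, while DESeq2 called all of them (adjusted p from 3.9e-11 for Ube2e2 to 0.0403 for Vldlr). In simulated counts of the HSC design DESeq2 made 53 false calls and edgeR 4, so calls by DESeq2 alone are weak evidence.

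edgeR called 0 of 14992 genes in HSC, with 538 at an unadjusted p under 0.05. DESeq2 called 21 genes, 13 higher and 8 lower, and limma on log2 TPM called 1, Ube2e2. Without HSC knockout replicate 1, edgeR called 2 genes, Fam118a (-2.45) and Ube2e2 (-2.06), each with an adjusted p of 0.00802. Over 16 alternatives the adjusted p of Fam118a lay between 1.3e-09 and 0.999 and that of Ube2e2 between 3.9e-11 and 0.999, with 3 alternatives past the threshold for each. Groups did not overlap for 773 genes, 5.16% of those tested, where chance gives 5.71%. In simulated counts of this design, edgeR recovered 43 of 100 genes changed 2-fold and 86 of 100 changed 4-fold. All were changed in the same data, and an adjusted p is easier to reach when many genes change. These counts therefore do not give the recovery where few genes change.

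**Figure D2:**
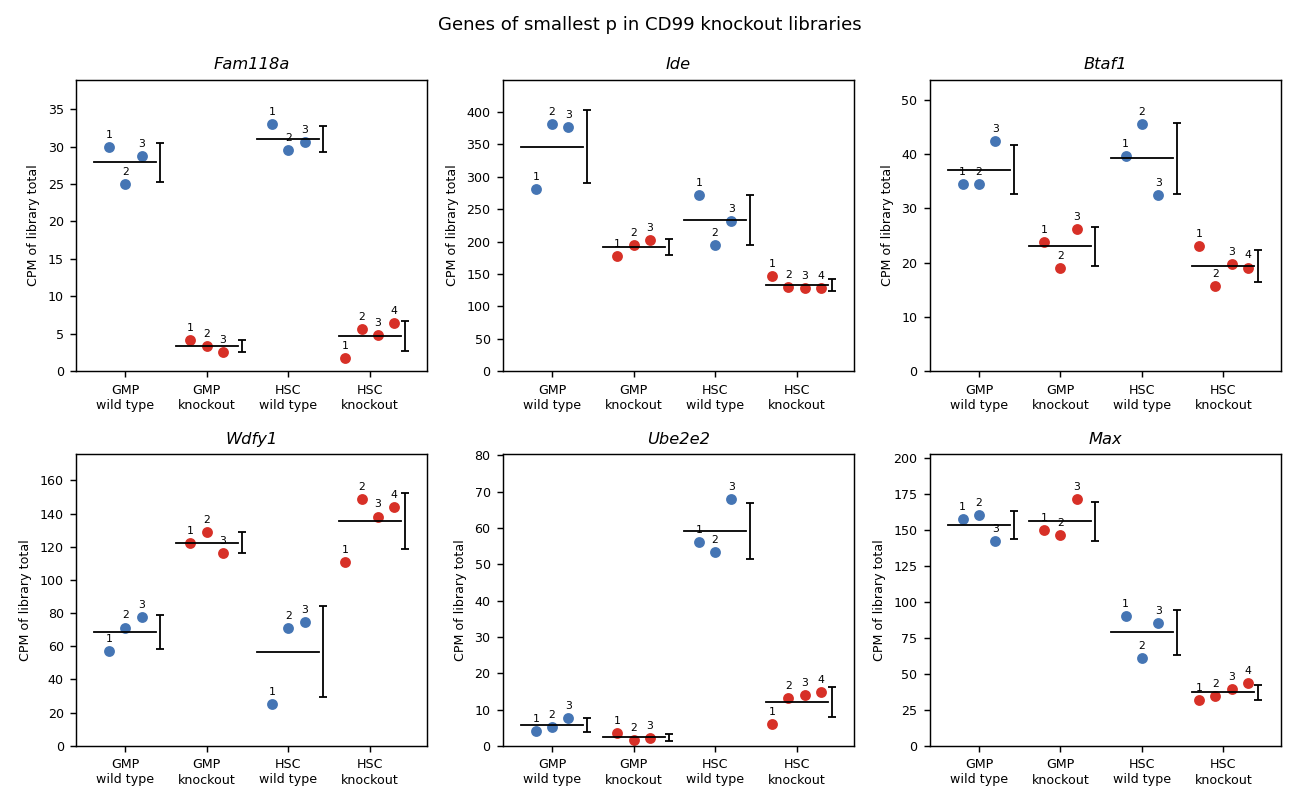
CPM of library total (linear axis) of Fam118a, Ide, Btaf1, Wdfy1, Ube2e2 and Max in each library, as points numbered by replicate with the group mean as a line and the SD as a bar, wild type in blue and knockout in red. Fam118a lay between 25.0 and 33.0 in the 6 wild-type libraries and between 1.82 and 6.39 in the 7 knockout libraries.

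In knockout HSC, 13 lists passed with the preset correlation (10 higher, 3 lower) and none with an estimated correlation. There were 6 lists past the threshold without wild-type replicate 3 or without knockout replicate 1, 8 without wild-type replicate 1 and 20 without knockout replicate 4. GMP and primary granule genes were higher for 23 of 26 members, with a median log2 fold change of 0.66 (adjusted p = 2.4e-05; adjusted p = 0.784 with an estimated correlation). The call held with each library left out, at 0.39 without knockout replicate 1. Fitted fold changes gave a median of 0.47 (0.36 to 0.47 over scalings). Mpo had 9.78 CPM in wild type and 62.2 in knockout, far under its 55016 in wild-type GMP. The groups overlapped for Mpo. In CPM of library total it had 2.23, 4.52 and 22.9 in wild type and 108, 37.0, 82.9 and 17.8 in knockout. Heat shock chaperones were higher for 21 of 23 members, with a median of 0.22 (adjusted p = 0.00242; adjusted p = 0.784 with an estimated correlation), also with each library left out, at 0.13 without knockout replicate 1. The knockout libraries differed in direction: the list score of replicate 2 lay below the wild-type mean, and those of the other knockout libraries above it. Hspa8 had 2585 and 3405 CPM and Dnaja1 489 and 722. Hspa1b was the 1 gene higher when adjusted over the list alone, against 0 over all genes tested by edgeR. Hspa1b and its near-identical paralog Hspa1a share reads, so their separate values are uncertain. The HSC-enriched list was lower for 30 of 40 members, with a median of -0.097 (adjusted p = 0.0130; adjusted p = 0.784 with an estimated correlation) and Hlf at 499 and 358 CPM. That call ended without wild-type replicate 3 (-0.10) or knockout replicate 1 (-0.00076), and the median was -0.17 without knockout replicate 4.

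Lists of protein synthesis and turnover were called in both directions in knockout HSC with the preset correlation. Cytosolic ribosomal protein genes were lower for 73 of 82 members, with a median of -0.072 (adjusted p = 8.4e-04; adjusted p = 0.784 with an estimated correlation). Rpl7 had 648 CPM in wild type and 574 in knockout. The call ended without wild-type replicate 3 (-0.038) or knockout replicate 4 (-0.023). The median was -0.11 without wild-type replicate 1, -0.047 without knockout replicate 2 and -0.12 without knockout replicate 3. Aminoacyl-tRNA synthetases were higher for 19 of 22 members (median 0.096, adjusted p = 0.0130) and unfolded protein response genes for 30 of 40 (median 0.10, adjusted p = 0.0130), each with an adjusted p = 0.784 with an estimated correlation. Neither passed without wild-type replicate 2 (0.068 and 0.096), wild-type replicate 3 (0.089 and 0.097) or knockout replicate 1 (0.067 and 0.081), and the unfolded protein list had 0.17 without wild-type replicate 1. Proteasome genes were higher for 37 of 43 members (median 0.087, adjusted p = 0.00923; adjusted p = 0.784 with an estimated correlation). They were not past the threshold without wild-type replicate 1 (0.070) or knockout replicate 1 (0.024), and had 0.14 without knockout replicate 4. Ribosome biogenesis genes had a median of 0.068 (adjusted p = 0.0369; adjusted p = 0.784 with an estimated correlation). They did not pass without wild-type replicates 1 (0.044), 2 (0.069) or 3 (0.063), or knockout replicates 1 (0.064) or 3 (0.039). Mitochondrial ribosomal protein genes had a median of 0.049 (adjusted p = 0.0227; adjusted p = 0.784 with an estimated correlation). They did not pass without wild-type replicate 1 (0.024) or knockout replicates 1 (-0.010), 2 (0.070) or 3 (0.048), and had 0.11 without knockout replicate 4. MYC targets (median 0.094, adjusted p = 0.0526) and translation factors (median 0.054, adjusted p = 0.277) did not pass. Max was the 1 gene lower in the MYC list when adjusted over the list alone, against 0 over all genes tested by edgeR.

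The remaining lists called in HSC did not keep their call without knockout replicate 1. Mitosis genes were higher for 38 of 40 members, with a median of 0.23 (adjusted p = 0.0130; adjusted p = 0.784 with an estimated correlation). Without that library the list was lower, at -0.12 and past the threshold. It did not pass without wild-type replicate 1 (0.23) or 3 (0.20), and had 0.47 without knockout replicate 4. Its fitted fold changes gave a median of 0.40 (0.24 to 0.40 over scalings). Late neutrophil genes had a median of 1.43 (adjusted p = 0.0266; adjusted p = 0.784 with an estimated correlation). In it 2 of 14 members were at 0 in every wild-type library, and the median was the same with these at their bounds. The list did not pass without knockout replicate 1 (0.083), knockout replicate 3 (0.84) or wild-type replicate 1 (1.24), and had 2.23 without knockout replicate 4. Fitted fold changes gave 3.19, with 0.77 to 3.22 over scalings. Erythroid genes had a median of 0.23 (adjusted p = 0.0292; adjusted p = 0.784 with an estimated correlation). They did not pass without wild-type replicates 1 (0.30) or 3 (0.12) or knockout replicates 1 (0.18) or 2 (0.16), and had 0.35 without wild-type replicate 2. Nuclear-retained RNAs were lower for 7 of 8 members, with a median of -0.42 (adjusted p = 0.0130; adjusted p = 0.784 with an estimated correlation) and Malat1 at 1946 and 1366 CPM. They did not pass without wild-type replicate 3 (-0.47) or knockout replicate 1 (-0.34), and had -0.28 without knockout replicate 2.

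**Figure D3:**
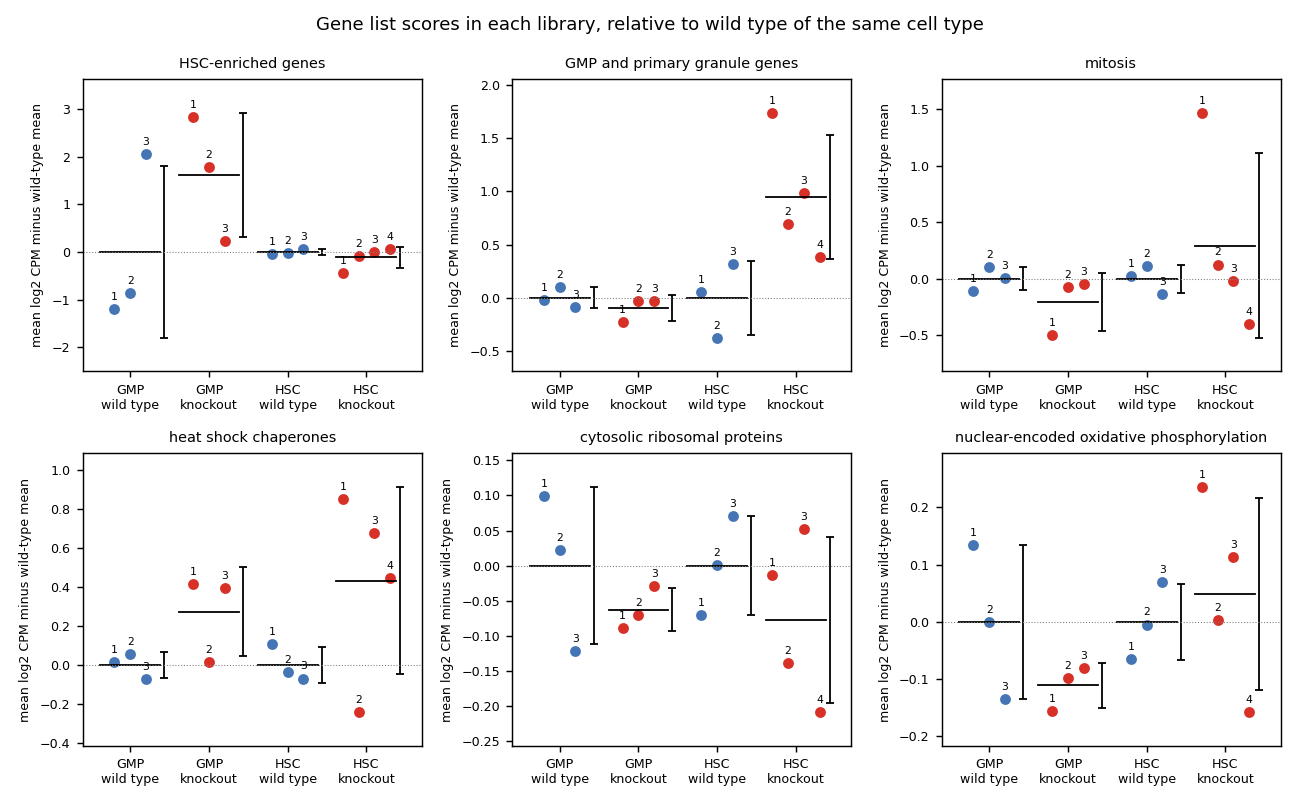
Score of 6 gene lists in each library (mean log2 CPM of the list's genes minus the wild-type mean of the same cell type), as points numbered by replicate with the group mean as a line and the SD as a bar, wild type in blue and knockout in red. In HSC the granule gene score lay between 0.38 and 1.74 in the 4 knockout libraries and between -0.37 and 0.32 in the 3 wild-type libraries.

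Whether the knockout effect differed between HSC and GMP was tested as an interaction. No gene passed. edgeR called 0 of 15693 genes, with 622 at an unadjusted p under 0.05. DESeq2 called 13 and limma on log2 TPM 1. In simulated counts of this design DESeq2 made 52 false calls and edgeR 5. The smallest p belonged to Tifab (log2 difference 4.28 ± 0.59, adjusted p = 0.15; called by DESeq2), with 0.0309 CPM in wild-type and 0.687 in knockout HSC, followed among expressed genes by Max (-1.10 ± 0.21, adjusted p = 0.875; called by DESeq2). In GMP the Max log2 fold change, chosen after its values were seen, was -0.0070 ± 0.11. Without GMP wild-type replicate 3 the count was 82, 81 of them with a lower effect in HSC. Without HSC knockout replicate 2 or 4 it was 1, Prss16 and Tifab in turn.

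With the preset correlation 12 lists were called as differing between the cell types (7 with a higher and 5 with a lower effect in HSC). None was called with an estimated correlation. Of 100 regroupings of the genotypes, 43 gave at least 12 lists, so chance was not excluded. HSC-enriched genes had a difference of -1.65 (adjusted p = 1.5e-08), mitosis genes 0.38 (adjusted p = 2.0e-06), oxidative phosphorylation genes 0.094 (adjusted p = 2.0e-06) and proteasome genes 0.12 (adjusted p = 8.2e-06), each with an adjusted p = 0.793 with an estimated correlation. Granule genes had a difference of 0.71 (adjusted p = 2.3e-07; adjusted p = 0.566 with an estimated correlation). The mitosis call ended without HSC knockout replicate 1 (0.037), and its difference was 0.69 without HSC knockout replicate 4. The other 4 calls held with each library left out. Of the values that moved most, the HSC-enriched difference was -0.78 without GMP knockout replicate 1, -0.99 without GMP wild-type replicate 2, -2.53 without GMP wild-type replicate 3 and -2.62 without GMP knockout replicate 3. The granule difference was 0.43 without HSC knockout replicate 1. Oxidative phosphorylation had 0.055 without GMP wild-type replicate 1. It and the proteasome list had 0.16 and 0.19 without HSC wild-type replicate 2, 0.21 and 0.20 without HSC wild-type replicate 3, 0.17 and 0.18 without HSC knockout replicate 2, and 0.25 and 0.25 without HSC knockout replicate 4. Cytosolic ribosomal protein genes (-0.071, adjusted p = 0.181), translation factors (median 0.0054, mean -0.0072, adjusted p = 0.309), ribosome biogenesis genes (0.036, adjusted p = 0.105) and MYC targets (median 0.045, mean -0.054, adjusted p = 0.127) were not shown to respond differently. Without GMP knockout replicate 1, 7 lists passed.

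Across 13191 genes measured in both cell types, no correlation between the knockout effects of GMP and HSC was detected. Pearson's r was -0.0079 (permutation p = 0.940) and Spearman's rho -0.054 (permutation p = 0.670), against 100 regroupings of the genotypes within each cell type; genes are not independent replicates. Without HSC knockout replicate 1, r was 0.083, and it was positive also without GMP wild-type replicate 1 (0.015), GMP knockout replicate 1 (0.022) or HSC wild-type replicate 1 (0.0063). No gene was called in both cell types by edgeR, while DESeq2 called 3 in both, Fam118a and Ide lower and Wdfy1 higher in knockout. At an unadjusted p under 0.005, 4 genes changed the same way in both, Fam118a, Ide and Btaf1 lower and Wdfy1 higher in knockout, where independence gives 0.0177 genes higher and 0.00872 lower. Wdfy1 in HSC had 56.0 CPM in wild type and 136 in knockout. Regrouped genotypes gave at most 2 such genes, and 1 of 100 groupings, the real one, gave 4 (permutation p = 0.010, the smallest that 100 regroupings can give). The count at this cutoff was chosen after the results were seen, so this p does not exclude chance.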

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

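Both tests of loss of CD99 as the source of HSC-type transcripts, the parting by library of the erythroid and megakaryocyte test, and both tests of the HSC library that stands apart were chosen only after the results were seen.

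Of 53 values tested for a library far from the rest among the 4 HSC knockout libraries, 4 had such a library, and the rule used (Dixon's, at its critical value for 4 samples) finds about 1 in 20 groups by chance. Knockout replicate 4 had 33.8 M (mega-) counts, against 27 to 28.1 M in the other 3. Knockout replicate 1 had a score of -0.64 for dendritic cell and MHC class II genes, against 0.043 to 0.13 in the others. It had 147 CPM of library total for Ide, against 128 to 130 in the others. It had 57.2 CPM of library total for Kif11, a mitotic kinesin, against 10.4 to 14.5 in the others.

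HSC knockout replicate 1 stood apart from the other HSC libraries on the first principal component, which held 28.3% of the variance in HSC. RNA from GMP-sorted cells was excluded as the whole source: mitosis genes implied a GMP share of 29.1%, whereas granule genes implied 0.635%, a ratio of 0.0218. CD34-positive progenitors in the sort are a candidate source, since Cd34, whose product the gate excludes, had 475 CPM of library total, 1.55 times the highest of the other 6 HSC libraries. The wild-type HSC libraries, sorted by the same gate, had 307, 209 and 173. This mRNA alone therefore does not mark cells outside the gate. More cells in division among true HSC in that sample, and a change caused by loss of CD99, stay open, although the other 3 knockout libraries did not share its Kif11 level of 57.2 CPM. Erythroid cells were not tested as a source, though Hbb-bs, a hemoglobin gene, had 40.8 CPM of library total there against 1.58 to 5.93 in the other 6, and the share of HSC-type transcripts was 73.9% against 97.9% or more.

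The effect of the knockout on 12 gene lists was called as differing between HSC and GMP by a test of the difference itself (limma camera, preset correlation). With an estimated correlation the adjusted p was 0.566 for granule genes and 0.793 for the other 11. Of 100 regroupings of the genotypes, 43 gave at least 12 lists, so chance was not excluded. The median differences (HSC minus GMP, log2) that held with each library left out were -1.65 for HSC-enriched genes, 0.71 for granule genes, 0.094 for oxidative phosphorylation and 0.12 for proteasome genes. Among these, the values that moved most were -2.62 and -0.78 for HSC-enriched genes without GMP knockout replicates 3 and 1, 0.43 for granule genes without HSC knockout replicate 1, 0.055 for oxidative phosphorylation without GMP wild-type replicate 1, and 0.25 for both oxidative phosphorylation and proteasome genes without HSC knockout replicate 4. Mitosis genes differed by 0.38, by 0.037 without HSC knockout replicate 1 and by 0.69 without HSC knockout replicate 4. Mitochondrial ribosomal protein genes differed by 0.081, and the call ended without GMP wild-type replicate 1 (0.021). Late neutrophil genes differed by 1.05, and the call ended without HSC wild-type replicate 1 (1.08) or HSC knockout replicate 1 (0.044). Megakaryocyte genes differed by -0.99, and the call ended without GMP wild-type replicates 1 (-0.35) or 2 (-0.24) or GMP knockout replicates 1 (-0.98) or 3 (-0.71). Interferon-stimulated genes differed by -0.37, and the call ended without GMP wild-type replicate 2 (-0.28), GMP knockout replicate 1 (-0.17) or HSC wild-type replicate 1 (-0.26). NF-kB targets differed by -0.97, and the call ended without GMP knockout replicate 1 (-0.31) or HSC wild-type replicate 1 (-0.60). S-phase genes differed by 0.13, and the call ended without GMP wild-type replicates 1 (0.13) or 2 (0.12), GMP knockout replicate 1 (0.076), HSC wild-type replicate 1 (0.12) or HSC knockout replicate 1 (-0.042). Immediate early genes differed by -0.64, and the call ended without GMP wild-type replicates 1 (-0.66) or 2 (-0.54), GMP knockout replicate 1 (-0.33), HSC wild-type replicate 1 (-0.25) or HSC knockout replicates 1 (-0.38) or 2 (-0.41). Calls that held but moved by over 1.5 times were mitochondrial ribosomal protein genes without HSC wild-type replicates 2 (0.13) or 3 (0.15) or HSC knockout replicates 2 (0.13), 3 (0.12) or 4 (0.20), and late neutrophil genes without HSC knockout replicates 2 (2.08) or 4 (1.84). The same holds for megakaryocyte genes without GMP wild-type replicate 3 (-1.79) or GMP knockout replicate 2 (-1.49), interferon-stimulated genes without GMP knockout replicate 3 (-0.59), and immediate early genes without HSC knockout replicate 4 (-1.01). It holds for NF-kB targets without GMP wild-type replicates 1 (-0.58) or 2 (-0.59) or HSC knockout replicates 1 (-0.54) or 2 (-0.57). It also holds for S-phase genes without GMP wild-type replicate 3 (0.075), HSC wild-type replicate 2 (0.20) or HSC knockout replicates 2 (0.23), 3 (0.20) or 4 (0.28).

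The HSC-enriched difference came from the GMP side, where wild-type replicate 3 and knockout replicates 1 and 2 held 8.70%, 17.6% and 6.89% of the HSC level of these genes, against 1.17% to 2.86% in the other 3 libraries. With any 1 library left out, others with these raised shares stayed in the fit. RNA from HSC-sorted cells is a candidate source: over 107 genes, at least 94.4% lay within 2-fold of the library's median share, as a single admixed profile would give, although the Sca-1 gate of the GMP sort would remove such cells. Erythroid or megakaryocyte progenitors, which the CD16/32 gate would remove, were excluded as the only source in knockout replicates 1 and 2. There the ratio of their genes' share to that of other HSC-type genes was 0.785 and 0.611, under the bound of 1.5. The 95% ranges, 0.733 to 0.847 and 0.388 to 0.828, are over genes of 1 library each, not over samples. As a part of the source these progenitors were not excluded. In wild-type replicate 3 they cannot be told apart from HSC, since the ratio was 1.65 and its range of 1.10 to 2.12 spans that bound, and in knockout replicate 3, which had few HSC-type transcripts, the ratio was 5.87 (3.44 to 21.1). Loss of CD99 as the source in all 3 libraries was excluded by the design, because wild-type replicate 3 is not a knockout. That library held 7.25 times the highest share of the other wild-type libraries. It was picked for its high share, so this ratio tests nothing about the knockout libraries. As a part of the source in the knockout libraries, loss of CD99 cannot be told apart from the rest. The exact two-sided permutation p of the share was 0.5, where 3 against 3 libraries cannot go below 0.1.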

How the results depend on the processing

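Among the alternatives, robust=TRUE, the HSC-share covariate, the fits without the libraries that stand apart and all values of the average effect were chosen only after the results were seen.

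The wild-type comparison called 7926 genes, and every alternative tried stayed within 1.5 times that count (6236 to 9179). In the GMP knockout (1 gene), 8 passed with DESeq2, 2 with limma on log2 TPM, 0 with all 13 libraries in 1 fit, 0 without the libraries that stand apart and 0 to 1 with 1 library left out (0 without wild-type replicates 1, 2 or 3 or knockout replicate 2); RLE, upper quartile, both filters, a threshold of 0.1, robust=TRUE and the covariate gave 1. In the HSC knockout (0 genes), 21 passed with DESeq2, 1 with limma on log2 TPM, 3 with all 13 libraries in 1 fit and 0 to 2 with 1 library left out (2 without knockout replicate 1). For the difference of effects (0 genes), 13 passed with DESeq2, 1 with limma on log2 TPM, 73 without the libraries that stand apart and 0 to 82 with 1 library left out (82 without GMP wild-type replicate 3, 1 without HSC knockout replicate 2 or 4). For the average effect (2 genes), 39 passed with DESeq2, 5 with upper-quartile factors, 4 with no filter, 4 at a threshold of 0.1, 4 with robust=TRUE, 81 without the libraries that stand apart and 1 to 68 with 1 library left out. It was 68 without GMP wild-type replicate 3, 6 without HSC knockout replicate 1, 4 without HSC knockout replicate 2 or 4, and 1 without GMP wild-type replicate 2, GMP knockout replicates 1, 2 or 3 or HSC wild-type replicate 3. The knockout fits without the libraries that stand apart keep 1 GMP knockout library, replicate 3, so their spread comes from the other groups and their values do not bear on stability. The cause was not tested for these changes, except that a threshold of 0.1 admits more genes by construction. With the replicate number as a block, 0 genes passed in GMP and 0 for the average effect.

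Lists passed in 0 cases with an estimated correlation and 0 with fry in all 3 comparisons. In GMP (15 lists), 7 passed with the covariate and 6 to 17 with 1 library left out (6 without wild-type replicate 1, 7 without knockout replicate 1). In HSC (13), 6 to 20 passed (6 without wild-type replicate 3 or knockout replicate 1, 8 without wild-type replicate 1, 20 without knockout replicate 4). For the difference of effects (12), 5 passed without the libraries that stand apart and 7 to 18 with 1 library left out (7 without GMP knockout replicate 1). Reversed were the interferon list in GMP, by test direction, with medians of 0.086 to 0.49 with 1 library left out (0.086 without knockout replicate 1), 0.087 without the libraries that stand apart and -0.023 with the covariate; mitosis genes in HSC without knockout replicate 1 (-0.12, range with 1 library left out -0.12 to 0.47); and, for the difference of effects, S-phase genes without HSC knockout replicate 1 (-0.042, range -0.042 to 0.28) or without the libraries that stand apart (-0.070), and mitosis genes without the latter (-0.099). The overlap correlation of -0.0079 became 0.041 over genes with a mean log2 CPM of at least 4 and lay between -0.052 and 0.083 with 1 library left out. The cause was not tested.

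Of the values for named genes under alternatives, 2371 for the wild-type populations, 2488 in GMP, 2301 in HSC and 3218 for the difference of effects kept direction and side of the threshold. For the wild-type populations 19 lost a call and 7 gained one; in GMP 7 lost a call, 6 gained one and 19 changed sign without a call; in HSC 17 gained a call and 6 changed sign without one; for the difference of effects 15 gained a call and 12 changed sign without one. No alternative was run for Cd99, which is not analysed here. edgeR recovered 65 of 100 simulated 2-fold changes in GMP, 43 in HSC and 25 for the difference of effects. No smaller change was simulated, nor data in which only a few genes changed.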

Other observations

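The count of genes past an unadjusted p of 0.005 in both cell types was chosen only after the results were seen. So were both tests of copy number and the average effect. The other groupings for genes in the HSC knockout, the difference of effects and the average were also chosen then.

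Fam118a, Ide, Btaf1 and Wdfy1 changed the same way in both cell types at an unadjusted p under 0.005. Of 100 regroupings 1, the real one, gave as many as 4 such genes, and the highest other gave 2. This count was chosen after the results were seen, and the labels do not say whether both populations came from the same animals. The count was rare among the regroupings, but chance is not excluded by it. With both cell types averaged, edgeR called Fam118a (log2 -2.87 ± 0.25, adjusted p = 0.00122) and Ide (-0.81 ± 0.10, adjusted p = 0.0185), though Fam118a alone passed without GMP wild-type replicate 2, GMP knockout replicates 1, 2 or 3 or HSC wild-type replicate 3 (1 gene each), and 20 of 100 regroupings gave as many genes, up to 701, so chance was not excluded for that count. A single loss of 1 copy from Btaf1 to Ide was excluded if the mouse gene order is as the human, where March5 lies between them, since March5 had log2 fold changes of -0.076 ± 0.10 in GMP and 0.073 ± 0.11 in HSC, at least 9.13 SE from -1. Copy-number differences of Ide, Btaf1 and Fgfbp3 without the genes between them are a candidate explanation that these values do not decide. In GMP and HSC the log2 fold changes were -0.89 and -0.79 for Ide, -0.72 and -0.99 for Btaf1 and -0.22 ± 0.34 and -1.01 ± 0.27 for Fgfbp3. Fgfbp3 in GMP lay farthest from -1, at 2.32 SE, and so failed the limit of 2 first set. It was under a limit of 2.64 for the 6 values, set only after the result was seen. Kif11 and Hhex follow Ide in the human order and would be unchanged under this explanation. Kif11 had log2 fold changes of -0.29 ± 0.20 in GMP and 0.51 ± 0.58 in HSC. The HSC value lay 2.60 SE from -1, so the wider limit would also pass Kif11 as a lost copy. Hhex had -0.12 ± 0.15 and -0.063 ± 0.13. Copy-number differences cannot be told apart from regulation or a strain variant, because the SE of Fgfbp3 is wide and mouse coordinates were not used here. For Fam118a none of these explanations was tested, so its lower level is not shown to follow from loss of CD99.

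Other groupings of the libraries gave these counts. In GMP, 2 of the 10 splits of the 6 libraries gave at least the real count of 1 gene, the highest other being 289, and 3 of 10 gave at least the real 15 lists, the highest other being 21; the split with 289 genes and 21 lists put wild-type replicate 3 with knockout replicates 1 and 2, which points to a structure of the samples other than genotype. For the wild-type populations 1 of 10 splits gave 7926 genes, the real one, and the highest other gave 0. These 10 splits are too few for a share under 0.05. In HSC, 10 of 35 splits gave at least the real 13 lists, the highest other being 21, so chance was not excluded. For the difference of effects 43 of 100 regroupings gave at least the real 12 lists, the highest other being 25, so chance was not excluded. The real gene counts of 0 in these comparisons are reached by every split (35 of 35 in HSC, the highest other 4, and 100 of 100 for the difference of effects, the highest other 783), so they test nothing about chance. The regrouping with 783 genes again set GMP wild-type replicate 3 and knockout replicates 1 and 2 against the other 3 GMP libraries, the same structure of the samples.

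Heat shock transcripts varied between libraries of 1 group. Hspa1b had 7.65, 7.40 and 4.48 CPM of library total in wild-type HSC and 167, 9.83, 114 and 51.7 in knockout HSC, and 86.1, 34.5 and 29.5 in wild-type and 125, 31.7 and 252 in knockout GMP. The chaperone list score of HSC knockout replicate 2 was -0.24, while the other 3 knockout libraries had 0.85, 0.67 and 0.44. In GMP the list was not past the threshold (median 0.10, adjusted p = 0.0652).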
